A study of Mus musculus with 16 samples.

How the data were processed

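Whole-liver RNA of 16 samples was measured, 4 in each of 4 groups: WT untreated, WT with 1 mg/kg LPS, S534A untreated and S534A with 1 mg/kg LPS. Groups and replicate numbers come from the sample titles. The series text describes the untreated S534A group with the LPS dose as well, and the titles and source names of those samples, which call them untreated, were followed. Per the labels' protocols, RNA was column-purified, amplified and biotin-labelled with a whole-transcript kit. The deposited values are on a log2 scale, and RMA (background correction, quantile normalization and median polish) is named in the submitters' processing notes. Its software version and probe set level are not given in the sources used here. The values ran from 3.49 to 14.54, which fits a log2 scale, and array medians from 6.25 to 6.42. No scanner files were used here, so signal over background per probe was not assessed, and the number of arrays limits the precision.

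The table held 35556 probe sets. The platform annotation gave 21789 of them 1 gene symbol, 1621 several and 12146 none. Symbols were checked by gene identifier against the RefSeq genes of GRCm38.p6, where 21698 matched and 0 symbols changed. That assembly was used for names, gene lengths and which genes share a chromosome, and none of its coordinates is printed. A probe set was kept when its value lay above the 30th percentile of its array in at least 4 of the 16 arrays, which 26037 did. Probe sets with several symbols or none were left out of the gene tests. A gene with several probe sets was represented by the probe set of highest mean, which left 15908 genes.

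Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) with 4 group means over all 16 arrays and no covariate, which gave 12 residual degrees of freedom and a prior of 4.28. The 5 comparisons were LPS against untreated in WT and in S534A, S534A against WT after LPS and without treatment, and the interaction, the LPS effect in S534A minus that in WT. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 15908 genes with a threshold of 0.05. The median standard error of a change was 0.099 (interaction 0.140), so a 95% interval spans about 0.21 (0.30) either way. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

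The design, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Of 28 lists 17 are pathways: NF-kB target genes, cytokines and chemokines, acute-phase proteins, interferon-stimulated genes, antigen presentation, TLR4 signalling components, complement and coagulation factors, drug-metabolising enzymes, bile acid synthesis and transport, fatty acid oxidation, lipogenesis, cholesterol synthesis, gluconeogenesis and amino acid catabolism, ER stress response, cell death and survival, cell cycle and circadian clock genes. The other 11 are markers of hepatocytes, Kupffer cells, neutrophils, monocytes, sinusoidal endothelium, stellate cells and fibroblasts, T and NK cells, B cells, cholangiocytes, erythroid cells and platelets, and pancreas and fat. They name 537 genes, of which 470 were measured, and some genes stand in more than 1 list. Several markers are also expressed by other liver cells. Each list was tested against all other genes with camera of limma at a preset correlation of 0.01, adjusted over the 28 lists of a comparison. Camera with a correlation estimated from the data and fry, which tests a list by itself, were alternatives. The mean of a list per array was compared by an exact permutation test over 70 arrangements, whose smallest two-sided p is 0.0286.

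Named genes in each comparison were Rela, the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap, up to 4 members of lowest p from each list and, where fewer than 5 genes passed, the 5 of lowest p as values. Predicted-gene, clone and small RNA symbols were not named under the second and last parts. From these, the genes in the text are a selection. A gene named in one comparison may be given in another. H2-Aa, Cdh5, Tnfaip2, Dbp and Arntl were chosen after their values were seen.

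Alternatives were no filter, a filter at the array median, the mean of a gene's probe sets, each probe set tested by itself, median centring, a second quantile normalization, array quality weights, a trended and robust eBayes, the replicate number as a block, only the 2 groups compared, a 1.5-fold minimum, an adjusted p threshold of 0.01 and leaving out each array in turn. After the data were seen, a clock score as covariate, leaving out 3 arrays with shifted clock genes, and removal of each array's trend with gene length were added, as was leaving out each array in turn for the lists other than NF-kB. The clock score was the mean of Dbp, Per1, Per2, Per3 and Tef minus Arntl. The 3 arrays left out were untreated WT arrays 1 and 3 and untreated S534A array 3, so the genotypes lost unequal numbers. Untreated S534A array 4, with a clock score of 0.96 and Arntl at 8.33, was kept. The steps were tested on simulated data for 15908 genes in 20 runs with 200 changed genes each. For S534A against WT after LPS, changes of 1.25-fold, 1.5-fold, 2-fold and 3-fold were recovered in 28.0%, 79.4%, 95.6% and 98.9% of cases, with 5.77% false among calls. For the interaction 6.9%, 48.9%, 86.7% and 97.2% were recovered, with 4.62% false. A list shifted by 1.25-fold was found in 20 of 20 runs for each, and 9 and 3 of 540 tests of other lists were called. The simulated genes varied independently of each other. These rates therefore do not cover lists whose genes vary together, as members of the lists may do in these data. The gene rates hold for 200 changed genes in a run. With fewer changed genes the adjusted p threshold is harder to reach, so they do not give the recovery of a few isolated changes.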

Results

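Gene expression was profiled in whole mouse liver on 16 Affymetrix whole-transcript arrays. Wild-type (WT) mice were compared with S534A mice, a knock-in line in which a serine of p65 is replaced by alanine at a phosphorylation site of the transactivation domain. The p65 protein is the NF-kB subunit encoded by Rela. Livers came from untreated males or from males given 1 mg/kg lipopolysaccharide (LPS), a bacterial endotoxin sensed through TLR4, with 4 samples in each of the 4 groups. The time between LPS and collection is not given in the sources used here. No group is labelled as given vehicle alone. Effects of handling, food intake or collection time therefore cannot be told apart from those of LPS. The labels do not state that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. In untreated arrays the clock score ran from −1.77 to 3.47 in WT and from −2.55 to 3.41 in S534A. That argues against a single liver measured 4 times in either untreated group, and the number of animals stays unknown. The median log2 value of an array lay between 6.25 and 6.42, and no value was missing. The first principal component held 78.5% of the variance and placed untreated arrays between −44.0 and −39.6 and LPS-treated arrays between 34.5 and 44.2. No arrays held identical values, and 15908 genes were tested. All changes below are on the log2 scale with the standard error of the limma fit (n = 4 per group), and the series title gives the question as the effect of the substitution on the response to LPS.

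Rela, the targeted gene, rose after LPS in both genotypes. Its log2 level was 10.03, 10.27, 10.06 and 10.34 in untreated WT arrays and 11.42, 11.31, 11.37 and 11.47 in LPS-treated WT arrays. In S534A livers it was 9.92, 10.00, 9.88 and 10.13 without treatment and 11.38, 11.43, 11.37 and 11.41 after LPS. The rise was 1.22 ± 0.08 in WT (2.33-fold, limma adjusted p = 1.66e-09) and 1.41 ± 0.08 in S534A (adjusted p = 2.75e-10). S534A and WT livers differed in Rela by 0.00 ± 0.08 after LPS and by −0.19 ± 0.08 without treatment (adjusted p = 0.486). The LPS effects differed by 0.19 ± 0.11 (interaction, adjusted p = 0.951). The targeted change is a point substitution, so the level of the transcript does not check the genotype labels.

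LPS raised interferon, chemokine, acute-phase and NF-kB genes in WT livers. The largest rises among genes whose groups did not overlap included Ifit2 (6.15 ± 0.12, 71.1-fold), Mx1 (6.04 ± 0.14) and Rsad2 (5.70 ± 0.15), all antiviral effectors, and A2m (5.51 ± 0.13), a plasma protease inhibitor. Cxcl10, a T cell chemoattractant, rose by 5.36 ± 0.11, Gbp5 by 5.39 ± 0.11, Slfn4 by 5.28 ± 0.11 and the serum amyloid Saa1 by 5.20 ± 0.37. Of the 31 measured NF-kB target genes 30 rose, among them the monocyte chemoattractant Ccl2 (4.29 ± 0.11), the NF-kB inhibitor Tnfaip3 (3.26 ± 0.09), the adhesion molecule Icam1 (2.65 ± 0.09), Nfkb2 (2.09 ± 0.09) and Birc3 (1.78 ± 0.08). The remaining member, Tnfaip2, named after its values were seen, stood at 0.58 ± 0.23 (limma adjusted p = 0.0544), and passed without untreated WT array 1 or 3, LPS-treated WT array 3 or untreated S534A array 1, 2 or 3 (0.0103 to 0.0475). It also passed with a filter at the array median, the clock score as covariate, the 3 arrays with a shifted clock left out, the length trend removed or only the 2 groups compared (0.000229 to 0.0471). All 29 interferon-stimulated genes and all 29 acute-phase genes rose, with Usp18 at 4.08 ± 0.08, Saa3 at 4.95 ± 0.15, the metal-binding Mt1 at 3.52 ± 0.15 and Stat3 at 1.68 ± 0.07. Of 33 cytokines and chemokines 24 rose, Ccl3 by 5.28 ± 0.12 and Ccl5 by 3.62 ± 0.10, and 2 fell, among them Ccl6 (−0.67 ± 0.13).

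Other groups of immune and stress genes moved in part after LPS in WT. Of 18 antigen presentation genes 10 rose, such as the peptide transporter Tap1 (3.09 ± 0.11) and the immunoproteasome subunit Psmb8 (1.74 ± 0.08). Another 4 of them fell, including the class II pathway genes H2-DMa (−1.15 ± 0.14) and H2-Aa (−0.75 ± 0.22, named after its values were seen). Of 21 TLR4 signalling components 10 rose, with the receptors Tlr2 (4.62 ± 0.10) and Cd14 (4.73 ± 0.21), the adaptor Myd88 (2.19 ± 0.08) and the inhibitor Irak3 (3.83 ± 0.10), and 1 fell, Irf3 (−0.39 ± 0.07). Of 23 cell death and survival genes 16 rose, including the necroptosis effector Mlkl (3.64 ± 0.14) and the inflammatory caspase Casp4 (2.81 ± 0.12), and none fell. Of 20 ER stress genes 7 rose, with Atf3 at 2.25 ± 0.28 and Chac1 at 1.59 ± 0.12, and Trib3 fell by 0.40 ± 0.12, a call lost with array quality weights (adjusted p = 0.0524), and by 0.62 without the 3 arrays with a shifted clock. Against all other genes, camera of limma gave adjusted p = 1.03e-28 for the NF-kB list, 1.33e-42 for interferon-stimulated genes, 2.61e-22 for acute-phase genes and 1.20e-17 for cytokines. It gave 1.05e-10 for cell death genes, 7.17e-06 for TLR4 components, 3.07e-05 for antigen presentation and 0.00366 for ER stress. The antigen presentation call was lost (adjusted p = 0.0508 with an estimated correlation), as was that of ER stress (adjusted p = 0.224 with an estimated correlation), and the other 6 held.

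In WT livers after LPS 18 of 20 cholesterol synthesis genes, 10 of 20 bile acid genes and 9 of 17 lipogenesis genes fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 5.01 ± 0.40 (32.2-fold), and the succinate receptor Sucnr1 (−3.31 ± 0.15), the iron exporter Slc40a1 (−3.16 ± 0.19) and the hepcidin regulator Hjv (−2.72 ± 0.16) fell as well. Further large falls were those of the potassium channel gene Kcnk5 (−3.63 ± 0.34) and Arrdc3 (−3.07 ± 0.29). Cholesterol synthesis genes that fell included Sc5d (−0.70 ± 0.08), Mvk (−1.19 ± 0.14) and Insig1 (−1.17 ± 0.16). Among bile acid genes Cyp8b1 fell (−1.30 ± 0.15), and the conjugating enzyme Baat rose by 0.76 ± 0.08. Among lipogenesis genes Gpam (−1.76 ± 0.11) and the regulator Srebf1 (−1.68 ± 0.21) fell, and 1 rose. The cholesterol list was lower than other genes by camera of limma (adjusted p = 0.000500), as were the bile acid (0.0477) and lipogenesis (0.0372) lists. All 3 calls were lost with an estimated correlation, with adjusted p = 0.423 with an estimated correlation for cholesterol, 0.224 for bile acids and 0.423 for lipogenesis. The bile acid call was also lost without LPS-treated WT array 3 or 4 or untreated WT array 2 or 4 (adjusted p from 0.0563 to 0.0903), and the lipogenesis call without LPS-treated WT array 1 or 3 or untreated WT array 2 (0.0511 to 0.0795). With each array centred on its median they stood at 0.0825 and 0.0865, with a filter at the array median at 0.143 and 0.117, and after a second quantile normalization at 0.147 and 0.0936.

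For 6 further lists the genes moved both ways after LPS in WT and the list as a whole was not called by camera. With fry, which tests a list by itself, fatty acid oxidation (adjusted p = 0.00320), cell cycle (0.0105) and drug metabolism (0.0156) lists passed as lower. By exact permutation of the list means, fatty acid oxidation, cell cycle and gluconeogenesis lists passed as lower (adjusted p = 0.0381 each). Fatty acid oxidation had 2 of 22 genes higher and 10 lower (limma camera adjusted p = 0.395), with its regulator Ppara at −0.92 ± 0.21. Drug-metabolising enzymes had 2 of 25 higher and 6 lower (adjusted p = 0.707), with the xenobiotic receptor Nr1i3 at −2.37 ± 0.25. Gluconeogenesis and amino acid catabolism had 2 of 15 higher and 3 lower (0.741), among them the glucose-releasing enzyme G6pc at −2.59 ± 0.26. Complement and coagulation had 4 of 27 higher, such as Cfb at 0.45 ± 0.06, and 5 lower (0.788). Cell cycle genes had 2 of 22 higher and 7 lower (0.97), with the replication factor Mcm7 at −0.58 ± 0.10. Circadian clock genes had 1 of 15 higher, Nfil3 at 2.07 ± 0.41, and 3 lower, Hlf among them at −0.86 ± 0.20 (0.884). Without the 3 untreated arrays with a shifted clock camera gave 0.0461 for this list, with a mean of −0.67. These arrays were picked on clock genes of this same list, so that value is no support for a fall.

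Most neutrophil markers rose after LPS in WT livers, while most Kupffer cell, sinusoidal endothelial and stellate cell markers fell. Of 12 neutrophil markers 10 rose, including S100a9 (2.92 ± 0.18, 7.59-fold) and Retnlg (2.47 ± 0.11), and camera of limma gave adjusted p = 4.64e-09, a call that held (adjusted p = 0.0208 with an estimated correlation). Of 7 monocyte markers 4 rose, such as Plac8 (2.42 ± 0.15), and Lyz2, which other myeloid cells share, fell by 0.87 ± 0.11 (adjusted p = 0.00744; adjusted p = 0.0870 with an estimated correlation). Of 13 Kupffer cell markers 11 fell, with Vsig4 at −2.19 ± 0.20, Cd5l at −1.76 ± 0.15 and Clec4f at −1.17 ± 0.10, and the scavenger receptor Marco rose by 1.28 ± 0.14 (adjusted p = 0.000737; adjusted p = 0.356 with an estimated correlation). Of 11 sinusoidal endothelial markers 9 fell, led by Kdr (−3.24 ± 0.12), Clec4g (−2.24 ± 0.12) and Tek (−2.13 ± 0.13), and Lyve1 rose by 1.35 ± 0.16 (adjusted p = 0.000117; adjusted p = 0.224 with an estimated correlation). The other riser, Cdh5, named after its values were seen, stood at 0.21 ± 0.08. Its call (adjusted p = 0.0397) was lost with median-centred arrays (0.11, adjusted p = 0.255), with array quality weights, the length trend removed or only the 2 groups compared (0.0536 to 0.108), and without any LPS-treated WT array or untreated WT array 1, 2 or 4 (0.0515 to 0.142). Of 12 stellate cell and fibroblast markers 9 fell, among them Hgf (−1.44 ± 0.13) and the retinol-storing enzyme Lrat (−1.55 ± 0.18) (adjusted p = 0.00133; adjusted p = 0.195 with an estimated correlation).

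The other cell type lists were not called after LPS in WT by camera of limma. B cell markers had 4 of 7 lower, such as Cd79b at −0.91 ± 0.11 (adjusted p = 0.110; 0.0452 with no filter), and T and NK cell markers had 1 of 8 higher, Gzmb at 1.17 ± 0.15, and 1 lower (0.977). Hepatocyte markers had 2 of 10 higher and 1 lower (0.723), cholangiocyte markers 1 of 4 higher and 1 lower (0.805), and erythroid and platelet markers 3 of 6 higher and 1 lower (0.149). None of the 7 pancreas and fat markers passed (0.689). In the T and NK, cholangiocyte, pancreas and fat, and gluconeogenesis lists the median and mean changes had opposite signs, and in the complement and hepatocyte lists both lay below 0 while the test pointed up relative to other genes. Adjusted over the list alone, NF-kB genes gave 31 higher, antigen presentation 6 lower, drug metabolism 4 lower, bile acids 11 lower, lipogenesis 10 lower, cell death 1 lower and T and NK cells 0 lower. The remaining counts were equal to those over all genes.

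In all, 7139 of the 15908 genes changed after LPS in WT (44.9%), 2377 higher and 4762 lower, with 712 and 585 of them at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). The share that rose depends on scaling and on which probe sets and changes are counted. It was 43.6% with every probe set tested by itself and 40.2% with a 1.5-fold minimum. Centring each array on its median moved the median change of all genes from −0.05 to −0.16 and gave 1838 higher and 6493 lower, or 22.1% higher in place of 33.3%.

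In S534A livers LPS again raised interferon, chemokine, acute-phase and NF-kB genes. Ifit2 rose by 6.07 ± 0.12, Mx1 by 6.06 ± 0.14, Cxcl10 by 5.37 ± 0.11, Saa1 by 6.26 ± 0.37 and Ccl2 by 4.39 ± 0.11. NF-kB genes rose in 30 of 31 cases, with Tnfaip3 at 3.30 ± 0.09, Icam1 at 2.85 ± 0.09 and Birc3 at 1.94 ± 0.08. Rel, itself an NF-kB subunit, stood at 0.16 ± 0.09 (limma adjusted p = 0.150; 0.0278 after a second quantile normalization). All 29 interferon-stimulated and all 29 acute-phase genes rose, as did 25 of 33 cytokines, 10 of 18 antigen presentation genes, 10 of 21 TLR4 components, 8 of 20 ER stress genes and 16 of 23 cell death genes. In those lists 2 cytokines, 4 antigen presentation genes, 2 TLR4 components, 0 ER stress genes and 1 cell death gene fell. Cyp7a1 (−5.99 ± 0.40), Kdr (−3.37 ± 0.12) and Slc40a1 (−3.19 ± 0.19) fell. All 20 cholesterol synthesis genes fell, along with 13 of 20 bile acid genes, 12 of 17 lipogenesis genes, 10 of 25 drug-metabolising enzymes, 8 of 22 fatty acid oxidation genes, 5 of 27 complement genes, 9 of 22 cell cycle genes, 4 of 15 gluconeogenesis genes and 5 of 15 clock genes. In the same lists 4 complement genes, 2 cell cycle genes, 1 bile acid gene, 1 drug-metabolising enzyme, 1 gluconeogenesis gene and 1 clock gene rose.

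Cell type markers after LPS in S534A gave 10 of 12 neutrophil markers higher, with S100a9 at 2.87 ± 0.18, and 5 of 7 monocyte markers higher and 1 lower. Of the Kupffer cell markers 11 of 13 fell and 1 rose, Vsig4 at −2.52 ± 0.20, of the sinusoidal endothelial markers 9 of 11 fell and 2 rose, and of the stellate markers 9 of 12 fell. Erythroid and platelet markers rose in 5 of 6 cases (limma camera adjusted p = 0.0338; adjusted p = 0.204 with an estimated correlation; 0.0649 without LPS-treated S534A array 1; 0.0607 with the length trend removed). B cell markers had 3 of 7 lower, T and NK cell markers 1 of 8 higher, hepatocyte markers 1 of 10 lower, cholangiocyte markers 1 of 4 higher and 1 lower, and pancreas and fat markers 0 of 7 either way. Camera of limma called the NF-kB list (adjusted p = 1.51e-26), interferon-stimulated (2.40e-41), acute-phase (8.81e-22), cytokine (5.37e-16), cell death (1.64e-09) and neutrophil (1.80e-09) lists, and these held with an estimated correlation.

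Several list calls in S534A did not hold with an estimated correlation. Camera of limma gave adjusted p = 3.47e-05 for antigen presentation (adjusted p = 0.0599 with an estimated correlation), 0.000124 for TLR4 components (0.0707 with it) and 0.00187 for ER stress (0.204 with it). Cholesterol synthesis stood at adjusted p = 6.31e-07 (0.235 with an estimated correlation), bile acids at 0.00284 (0.0878 with it) and lipogenesis at 0.00971 (0.303 with it, and 0.0523 with a filter at the array median). Kupffer cells stood at 0.000401 (0.299 with an estimated correlation), sinusoidal endothelium at 6.45e-05 (0.204 with it), stellate cells at 0.00401 (0.204 with it) and monocytes at 0.00971 (0.0950 with it). The lists not called by camera ranged from drug-metabolising enzymes (0.0722, with 0.0190 without LPS-treated S534A array 3 and 0.0194 with no filter) to complement (0.895). Median and mean differed in sign for hepatocyte, T and NK cell and cholangiocyte markers, and the complement test pointed up with both below 0. Adjusted over the list alone, the counts differed from those over all genes for cytokines (27 higher), bile acids (14 lower) and Kupffer cells (12 lower).

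In all, 7225 genes changed after LPS in S534A (45.4%), 2258 higher and 4967 lower, with 680 and 677 at least 2-fold (limma). Median centring gave 21.5% higher among 7934 calls in place of 31.3%, and moved the median change of all genes from −0.03 to −0.13. The share was 40.0% with every probe set tested by itself and 35.2% with a 1.5-fold minimum. The 2 LPS comparisons share no array. Across genes, which are not independent replicates, their log2 changes had r = 0.964 and rho = 0.900. Of 5982 genes called in both, 5980 moved the same way, 1888 higher and 4092 lower, where independent lists would share 337 and 1487. Of the 1295 genes called and changed at least 2-fold for the mean LPS effect of both genotypes, 669 (51.7%) had the larger change in S534A.

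**Figure D1:**
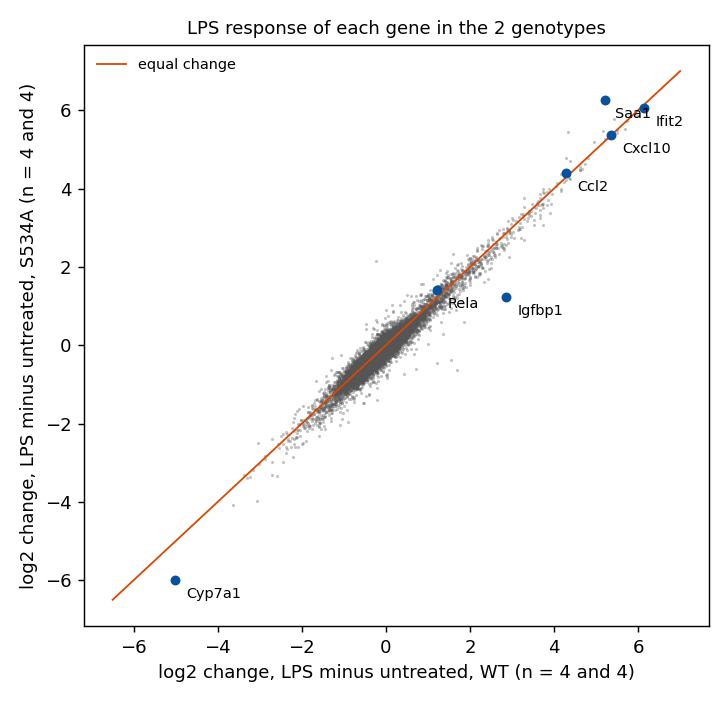
Each point is a gene, with its log2 change after LPS in WT livers on the x axis and in S534A livers on the y axis (n = 4 arrays per group). Points lie along the diagonal (r = 0.964 across genes), with Ifit2 at 6.15 and 6.07, Cyp7a1 at −5.01 and −5.99 and Igfbp1 at 2.87 and 1.24.

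**Figure D2:**
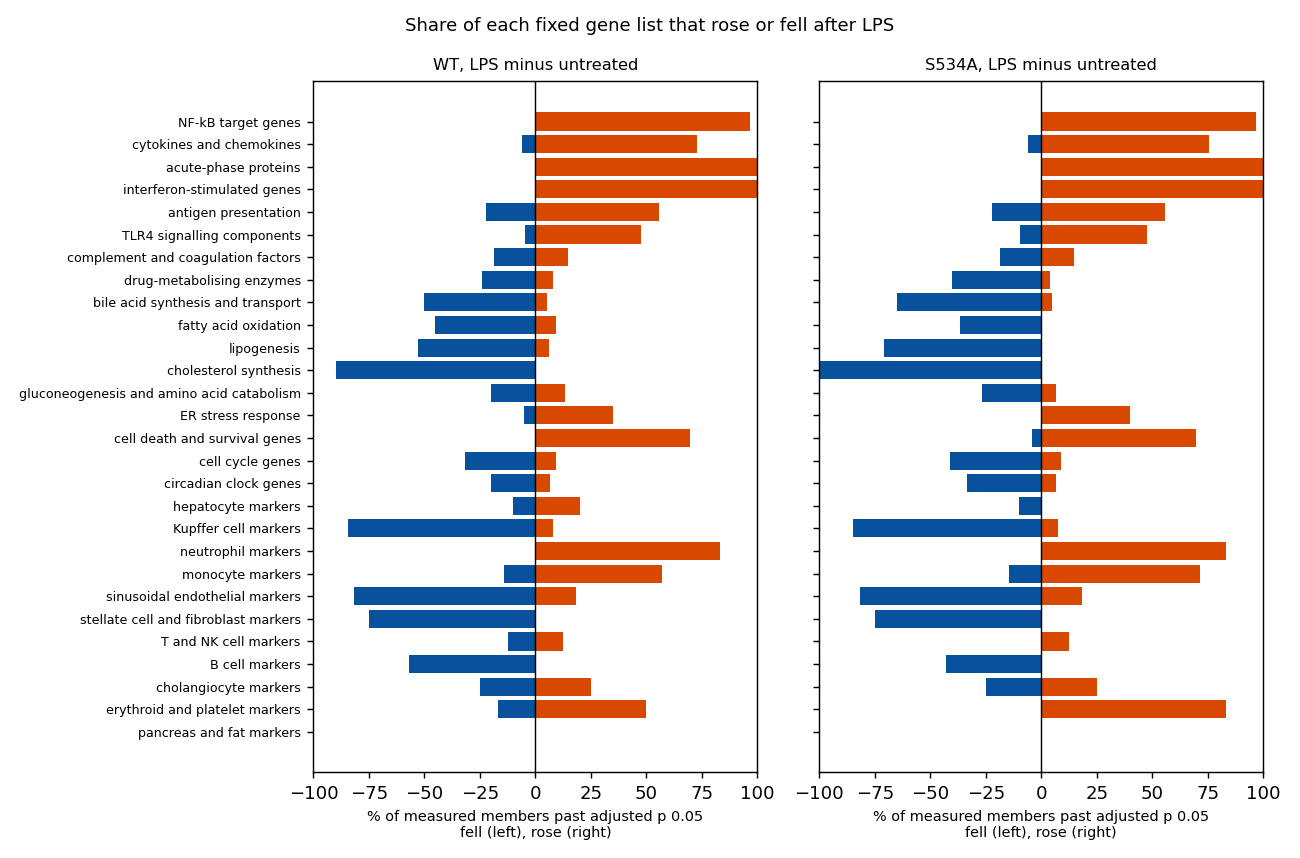
Share of the measured genes of each fixed list that rose or fell after LPS (limma adjusted p under 0.05), for WT and S534A livers. In WT 29 of 29 interferon-stimulated genes rose and 18 of 20 cholesterol synthesis genes fell, and in S534A 29 and 20.

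After LPS no gene passed the test between S534A and WT livers. Rela differed by 0.00 ± 0.08, and the NF-kB targets Ccl2, Tnfaip3, Icam1 and Nfkb2 rose by 4.39, 3.30, 2.85 and 2.09 in S534A against 4.29, 3.26, 2.65 and 2.09 in WT. The mean of the 31 NF-kB target genes was 9.55 ± 0.06 (SD, n = 4) in S534A and 9.58 ± 0.08 in WT arrays after LPS (two-sided exact permutation p = 0.486). The difference was −0.04, with a 95% interval of −0.13 to 0.06, and 21 of the 31 genes lay below 0 (limma camera adjusted p = 0.611). The NF-kB genes of lowest p included Birc3 at 0.17 ± 0.08 and Il6 at −0.40 ± 0.20. Of the 15908 genes 0 passed in limma, and 477 had an unadjusted p under 0.05 where 795.4 would by chance alone. The 5 named genes of lowest p were Gpr155 (0.39 ± 0.08), Cth (−0.30 ± 0.07), Tesmin (0.34 ± 0.08), Acss3 (−0.77 ± 0.17) and Tm4sf20 (0.48 ± 0.12). For 95.8% of genes the 95% interval of the difference lay within 1.5-fold either way.

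**Figure D3:**
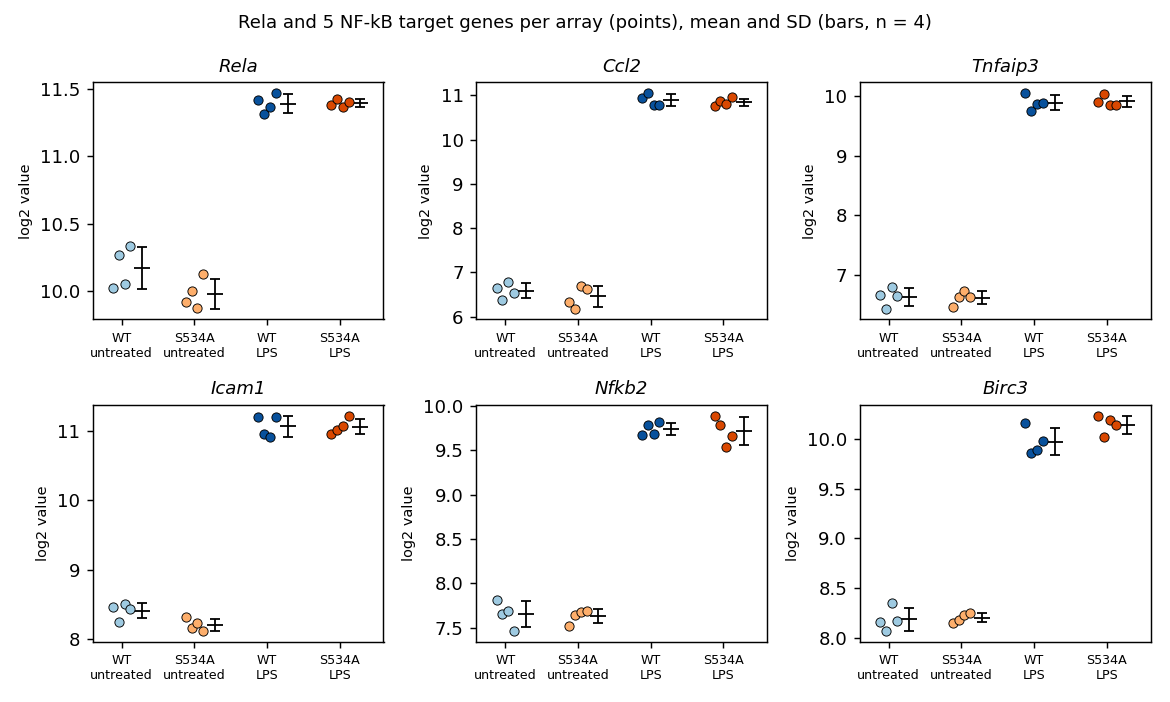
Log2 RMA value of Rela and 5 NF-kB target genes in each array, by group, with the mean and SD of the 4 arrays. Rela lay between 11.31 and 11.47 in the 8 LPS-treated arrays and between 9.88 and 10.34 in the 8 untreated arrays.

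In S534A livers after LPS 4 lists tested lower than in WT with no gene past the threshold over all genes. All 20 cholesterol synthesis genes lay below 0, among them Nsdhl (−0.39 ± 0.10), Sqle (−0.50 ± 0.17), Msmo1 (−0.41 ± 0.15) and Dhcr7 (−0.31 ± 0.11), with a mean of −0.28 (limma camera adjusted p = 7.61e-13; adjusted p = 0.541 with an estimated correlation). All 13 Kupffer cell markers lay below 0, such as Vsig4 (−0.48 ± 0.20), Marco (−0.35 ± 0.14) and Clec4f (−0.24 ± 0.10), with a mean of −0.22 (adjusted p = 1.60e-05; adjusted p = 0.844 with an estimated correlation). Sinusoidal endothelial markers lay below 0 in 9 of 11 cases, with Pecam1 at −0.31 ± 0.09 and Oit3 at −0.33 ± 0.10 (adjusted p = 0.0176; adjusted p = 0.918 with an estimated correlation). Monocyte markers did so in 6 of 7 cases, with Lyz2 at −0.33 ± 0.11 (adjusted p = 0.0493; adjusted p = 0.541 with an estimated correlation), so all 4 calls were lost with it. For the means per array the two-sided exact permutation p was 0.2 for cholesterol, 0.114 for Kupffer cells, 0.4 for endothelium and 0.0286, the smallest that 4 against 4 arrays can give, for monocytes. Adjusted over the 28 lists these were 0.72, 0.72, 0.8 and 0.72. Adjusted over the list alone, 1 cholesterol gene and 2 endothelial genes were lower and no member of any other list passed. The endothelial call was lost without LPS-treated S534A array 1 (adjusted p = 0.174) or 2 (0.215) or LPS-treated WT array 2 (0.501), with a filter at the array median (0.0519) or without the 3 arrays with a shifted clock (0.0538). The endothelial mean moved from −0.11 to −0.03 without LPS-treated WT array 2, to −0.07 without LPS-treated S534A array 1 and to −0.17 without array 4. The cholesterol mean was −0.18 without LPS-treated S534A array 1, the Kupffer mean −0.14 without array 2, and the monocyte mean moved from −0.14 to −0.09 without LPS-treated WT array 2. The monocyte call was lost without untreated WT array 1 or 3, LPS-treated WT array 2, 3 or 4, LPS-treated S534A array 1, 2 or 4 or untreated S534A array 4 (0.0502 to 0.188), and with no filter, a filter at the array median, median centring, the length trend removed or the 3 shifted-clock arrays left out (0.0507 to 0.0867). The 24 other lists were not called, with acute-phase, lipogenesis, cell death, stellate, and T and NK cell lists opposite in the sign of median and mean.

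Without treatment 2 genes passed the test between genotypes. Rela differed by −0.19 ± 0.08 and did not pass. Igfbp1, an insulin-repressed IGF binding protein, was higher in S534A livers by 2.00 ± 0.26 (3.99-fold, limma adjusted p = 0.0168), with log2 values of 11.31, 11.60, 12.02 and 11.78 against 9.53, 10.52, 9.60 and 9.06 in WT. Mrps18a, a mitochondrial ribosomal protein, stood at −0.53 ± 0.08 relative to WT (adjusted p = 0.0344), and Ndufa2 (−0.44 ± 0.08, 0.111), Abhd17a (−0.40 ± 0.07, 0.111) and Dpm3 (−0.35 ± 0.06, 0.117) followed without passing. With array quality weights these 3 passed (0.0103, 0.0161 and 0.0131), Ndufa2 and Dpm3 also with median centring (0.0463 each) and Ndufa2 without LPS-treated WT array 2 (0.0495). The NF-kB genes Rel (0.37 ± 0.09, adjusted p = 0.175; 0.0421 with array quality weights) and Irf1 (−0.50 ± 0.14) were among the lowest p of their list, and the list as a whole was not called (0.919). An unadjusted p under 0.05 was reached by 1412 genes. The Igfbp1 call was lost without untreated WT array 1 (adjusted p = 0.106) or untreated S534A array 2 (0.0747), 3 (0.0521) or 4 (0.113), and the Mrps18a call without untreated WT array 1, 2 or 4, LPS-treated WT array 4, LPS-treated S534A array 1 or 2, or any untreated S534A array (0.0521 to 0.241). With only the 2 untreated groups in the fit both stood at 0.255, with the 3 shifted-clock arrays left out at 0.383 and 0.0612. With the replicate number as a block they stood at 0.0882 and 0.116.

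Between untreated genotypes 5 lists tested apart. Interferon-stimulated genes were lower in S534A as a list, with Bst2 at −0.36 ± 0.10 and Irgm1 at −0.29 ± 0.09 (limma camera adjusted p = 0.0141; adjusted p = 0.634 with an estimated correlation). Antigen presentation genes were lower too, with Psmb10 at −0.27 ± 0.09 and 17 of 18 members below 0 (adjusted p = 0.0348; adjusted p = 0.567 with an estimated correlation), as were Kupffer cell markers, with C1qa at −0.33 ± 0.11 (adjusted p = 0.0402; adjusted p = 0.928 with an estimated correlation). Drug-metabolising enzymes were higher with 21 of 25 members above 0 (adjusted p = 0.00678; adjusted p = 0.567 with an estimated correlation). Bile acid genes were higher with 18 of 20, such as the phospholipid exporter Abcb4 at 0.28 ± 0.10 (adjusted p = 0.00678; adjusted p = 0.531 with an estimated correlation), so all 5 calls were lost with it. No member of these 5 lists passed over all genes or adjusted over the list alone. The change between untreated genotypes went with gene length (Spearman's rho = 0.28 across genes, which are not independent replicates), as it did in the interaction (−0.29). The rho was 0.0075 for LPS in WT, −0.099 for LPS in S534A and −0.106 between genotypes after LPS. The interferon call was also lost without untreated WT array 1 (0.154) or 4 (0.152) or untreated S534A array 2 (0.271), where its mean moved from −0.10 to −0.05 without WT array 1 or S534A array 2. That of antigen presentation was lost without untreated WT array 2 (0.0606) or 4 (0.362, mean from −0.11 to −0.06) or untreated S534A array 2 (0.271, mean −0.06) or 4 (0.0518). The Kupffer call was lost without untreated WT array 4 (0.646, mean from −0.14 to −0.05), LPS-treated WT array 2 (0.0636) or untreated S534A array 2 (0.698, mean −0.03), and that of drug metabolism without untreated WT array 1 (0.0762). Without the 3 arrays with a shifted clock the drug metabolism mean moved from 0.13 to 0.03 (0.783) and the bile acid call was lost (0.232), while the antigen presentation mean moved from −0.11 to −0.20 and the Kupffer mean from −0.14 to −0.21. The antigen presentation call was lost with a second quantile normalization (0.0512) and the length trend removed (0.10), and the Kupffer call with these, a filter at the array median or median centring (0.0545 to 0.0745). Other lists were not called, among them acute-phase genes with Saa1 at −1.06 ± 0.37 and Saa2 at −1.13 ± 0.38 (0.320), gluconeogenesis with Pck1 at 0.33 ± 0.14 (0.0633) and monocyte markers with Lyz2 at −0.45 ± 0.11 (0.124). With array quality weights Pck1 (0.52, adjusted p = 0.0347), Lyz2 (−0.45, 0.0303) and Abcb4 (0.37, 0.0421) passed. Adjusted over the list alone, 1 NF-kB gene was higher and 1 lower, 1 complement gene was higher and 1 monocyte gene lower. In the cytokine, TLR4 and cholangiocyte lists the median, mean and test did not share a sign.

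No gene passed the test of whether the LPS response differed between genotypes. Rela stood at 0.19 ± 0.11, and the NF-kB list at a mean of −0.03 with a 95% interval of −0.17 to 0.11 (limma camera adjusted p = 0.779), its members including Rel at −0.44 ± 0.13 and Irf1 at 0.56 ± 0.21. Igfbp1, which rose by 2.87 ± 0.26 in WT and by 1.24 ± 0.26 in S534A livers, had an interaction of −1.63 ± 0.37 (adjusted p = 0.875). The lowest p belonged to Polr2i (0.68 ± 0.14), Gstp1 (0.48 ± 0.10), Cth (−0.43 ± 0.10), Abhd17a (0.43 ± 0.10) and Zfp467 (0.49 ± 0.11), all at adjusted p = 0.875. Of the 15908 genes 0 passed in limma and 766 had an unadjusted p under 0.05. With array quality weights Polr2i (adjusted p = 0.00646) and Igfbp1 (0.00772) passed, and Polr2i also passed without LPS-treated WT array 2 (0.0198).

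Cholesterol synthesis, bile acid and drug metabolism lists tested lower in the interaction. Their means fell further after LPS in S534A than in WT. The mean change was −0.96 against −0.66 for cholesterol, −0.81 against −0.56 for bile acids and −0.32 against −0.13 for drug metabolism. Cholesterol genes had an interaction below 0 in 19 of 20 cases, such as Nsdhl (−0.53) and Cyp51 (−0.52 ± 0.19), with limma camera adjusted p = 7.45e-07 (adjusted p = 0.867 with an estimated correlation). Bile acid genes lay below 0 in 17 of 20 cases, with Cyp8b1 at −0.55 ± 0.22 and Akr1d1 at −0.31 ± 0.11 (adjusted p = 0.00255; adjusted p = 0.369 with an estimated correlation). Drug-metabolising enzymes did so in 20 of 25, with Cyp2b9 at −1.67 ± 0.59 and Cyp2b10 at −0.89 ± 0.40 (camera adjusted p = 0.0101, and 0.867 with an estimated correlation). Camera did not call this list as changed by LPS in either genotype, while fry called it lower in both (adjusted p = 0.0156 in WT and 0.000213 in S534A). The bile acid mean was higher in S534A by 0.13 without treatment and differed by −0.11 after LPS, and the drug metabolism mean by 0.13 and −0.07, and neither difference after LPS was called. The interaction also went with gene length (Spearman's rho = −0.29 across genes). The drug metabolism call was also lost without untreated WT array 1 (0.0922), untreated S534A array 3 (0.0704) or LPS-treated S534A array 1 (0.112) or 2 (0.0661), and with a filter at the array median (0.0711). Without the 3 arrays with a shifted clock the drug metabolism mean moved from −0.20 to −0.10 (0.449) and the bile acid call was lost (0.0598). The other 25 lists were not called, and median and mean had opposite signs in the complement, fatty acid oxidation, hepatocyte and monocyte lists. Adjusted over the list alone, 1 cholesterol gene was lower in the interaction. The 95% interval of the interaction lay within 1.5-fold for 82.0% of genes.

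**Figure D4:**
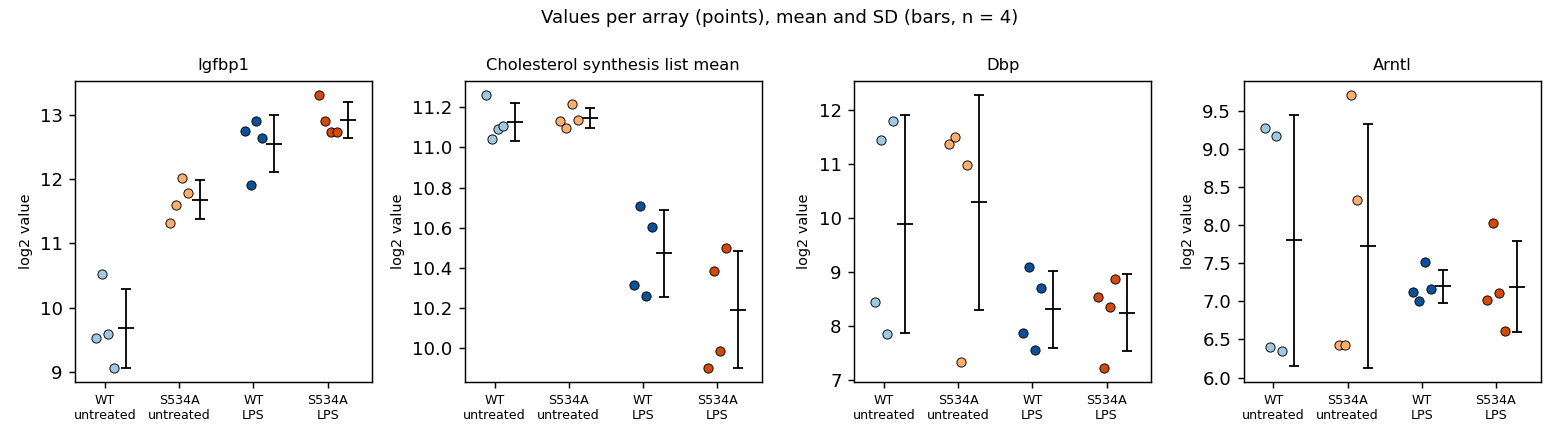
Log2 RMA value per array, by group, of Igfbp1, the mean of the cholesterol synthesis list, and the clock genes Dbp and Arntl, with the mean and SD of the 4 arrays. Untreated Igfbp1 lay between 11.31 and 12.02 in S534A and between 9.06 and 10.52 in WT, while untreated Dbp spread from 7.33 to 11.80 over both genotypes.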

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

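The tests of what lies behind the cholesterol difference after LPS were chosen after the result was seen, and the list tests of the interaction before. In this list of departures a value is the gap between an array and the nearest other of its 4, divided by the range of the 4. Chance puts about 1 in 20 groups past the limit, and 29 of 540 groups (5.37%) passed it where 27 were due by chance.

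Among list means, array 3 of LPS-treated WT stood high for acute-phase genes (0.877) and low for interferon-stimulated genes (0.839). Untreated S534A array 3 stood low for clock (0.909) and cell cycle genes (0.866), and LPS-treated S534A array 2 stood low for clock genes (0.887), cell cycle genes (0.861) and Kupffer cell markers (0.855). Kupffer cell markers were also low in untreated S534A array 2 (0.899), and bile acid genes in untreated S534A array 1 (0.911). These are 9 of 112 list means.

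Among genes in LPS-treated WT, array 3 was low for Cxcl10 (0.839) and H2-DMa (0.873), array 2 high for Arrdc3 (0.833), Hgf (0.855) and Gzmb (0.846), and array 4 high for Mvk (0.831) and low for Abcb4 (0.879). In untreated WT, array 4 was high for Myd88 (0.866) and Pecam1 (0.947), array 1 high for Sc5d (0.847) and array 2 low for Oit3 (0.972). In untreated S534A, array 2 was low for Cd5l (0.897), Pecam1 (0.877) and C1qa (0.896), array 3 high for Psmb8 (0.855) and low for Dbp (0.875), and array 1 high for Rel (0.873) and low for Gpam (0.865) and Cyp2b10 (0.912). Psmb8 was low in LPS-treated S534A array 3 (0.958).

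The LPS effect on 3 lists differed between genotypes by camera of limma in the interaction, with adjusted p = 7.45e-07 for cholesterol synthesis, 0.00255 for bile acids and 0.0101 for drug-metabolising enzymes, and none of the 3 held with an estimated correlation. Among probe sets without a gene name, which no gene comparison used, 1992 of 7635 were higher after LPS in WT, 817 were lower, and 1309 were higher in both genotypes.

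Cholesterol synthesis genes were lower in S534A than in WT livers after LPS in all 20 members, with a mean difference per array of −0.28 (95% interval −0.57 to 0.01). The difference was −0.18 (−0.47 to 0.11) without LPS-treated S534A array 1, the value nearest 0 of the 8, and −0.28 (−0.59 to 0.03) with the clock score as covariate. It stayed below 0 without each of the 8 arrays, from −0.18 to −0.38. The interval with all 16 arrays already reached past 0, so intervals that do so with 1 array left out single out no array. A single array is thus neither shown nor excluded as the cause. The clock score ran from −0.01 to 1.53 in LPS-treated WT and from −0.70 to 1.63 in LPS-treated S534A arrays. With that overlap the covariate could hardly move the difference, so its test does not decide on collection time. The exact permutation p of the list mean was 0.2, so a chance difference between arrays that the genes of the list share could account for the small p of camera, which at its preset correlation leaves that spread out. The first form of these tests used that list test, which stayed at adjusted p = 3.90e-06 or below without any of the 16 arrays, and was replaced after its values were seen for this reason. An effect of the genotype stays open.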

How the results depend on the processing

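The settings on the clock and on gene length, and leaving out each array for the lists other than NF-kB, were chosen after seeing the data. The ER stress list, not called between untreated genotypes with a mean of −0.06, passed as higher in S534A (0.085, adjusted p = 0.0384) without the 3 arrays with a shifted clock, and no called gene or list changed direction. LPS counts stayed within 1.5 times of those given except that in WT testing every probe set by itself gave 10870 and a 1.5-fold minimum 3158, and in S534A that minimum gave 3286, through more tests or fewer genes allowed. Leaving out 1 array gave 6514 to 7465 genes in WT and 6608 to 7659 in S534A. After LPS every probe set tested by itself gave 1 difference between genotypes, and 0 remained without any 1 array (0 to 0). The cause was not tested.

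Without treatment the 2 genes became 0 with every probe set tested, 0 with only the 2 groups compared, 0 at an adjusted p under 0.01, 1 with the 1.5-fold minimum, 1 without the 3 arrays with a shifted clock, 4 with median centring, 4 with trended and robust eBayes and 370 with array quality weights (215 higher, 155 lower). The weights ranged from 0.25 for LPS-treated WT array 2 to 3.475 for untreated S534A array 4, and that untreated count rests on them. Leaving out 1 array gave 0 to 7, with 7 without LPS-treated WT array 2 and a count beyond 1.5 times of 2 in 10 of the 16 settings. The interaction gave 3 genes with array weights and 0 to 2 without 1 array, with 2 without untreated WT array 4. Beyond the smaller tests, the cause was not tested.

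With the replicate number as a block 0 genes differed between untreated genotypes, where Igfbp1 had adjusted p = 0.0882 and Mrps18a 0.116. The numbers showed no consistent pairing of the samples, which does not exclude one. Same-number arrays correlated from −0.49 to 0.59 in their deviations, with a median of −0.05 against 0.03 for other numbers. Of 24 such pairs 9 lay over 0.1, and 6 of 16 arrays had their best partner under their own number. The NF-kB difference after LPS ran from −0.07 to −0.01 without 1 array (adjusted p 0.171 to 0.97), its interaction from −0.07 to −0.01 (0.0016 after a second quantile normalization, called in neither) and the exact p of its mean from 0.114 to 0.771.

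Counting each named gene under each setting once, genes kept their side of the threshold in 2075 cases for LPS in WT, 475 for LPS in S534A, 501 between genotypes after LPS, 446 without treatment and 402 in the interaction. They lost a call in 12 cases for LPS in WT and 20 without treatment, and gained one in 13, 1, 0, 10 and 3 in the order first given. Counted in that way, lists kept theirs in 671, 679, 642, 664 and 656 cases, lost a call in 22, 14, 27, 29 and 13 and gained one in the same direction in 7, 7, 6, 6 and 6. Values past the threshold in neither setting turned sign in 6 of the gene cases and 168 of the list cases. Of the lists not called after LPS between genotypes, neutrophil markers passed without LPS-treated WT array 2 (0.000161), and cytokines, drug metabolism, bile acids and erythroid markers without LPS-treated S534A array 3 (0.0342 each), cytokines also with a second quantile normalization (0.0467). Untreated, gluconeogenesis passed without untreated WT array 2 (0.0192) or LPS-treated S534A array 1 (0.0345) or with that normalization (0.0385), and monocytes without untreated S534A array 3 (0.0432). Without the 3 arrays with a shifted clock acute-phase genes (0.0311) and monocytes (0.0196) passed. In the interaction, gluconeogenesis passed without untreated WT array 2 (0.0227) or LPS-treated S534A array 1 (0.0101) or with that normalization (0.0405), endothelium without LPS-treated WT array 1 (0.0225) or LPS-treated S534A array 4 (0.0287) and Kupffer cells without untreated S534A array 2 (0.0317). With fry, which tests a list by itself, no list called between genotypes or in the interaction passed (0.201 to 0.799). After LPS drug metabolism, fatty acid oxidation, cell cycle and B cell lists passed with it in both genotypes, erythroid markers in WT and gluconeogenesis in S534A (1.36e-05 and 3.04e-06 for B cells in S534A and WT, 0.000213 to 0.0156 for the others). No scanner signal was used here, so the limit set by dim probes is unknown.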

Other observations

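The counts of other splits and the chromosome test in this part were set before their results were seen, and the tests of Igfbp1, of the clock settings and of chance agreement after. Dbp and Arntl, clock genes of opposite phase that were chosen after their values were seen, varied widely between untreated livers. Dbp had log2 values of 8.45, 11.45, 7.85 and 11.80 in untreated WT and 11.37, 11.50, 7.33 and 10.98 in untreated S534A arrays 1 to 4. Arntl had 9.27, 6.40, 9.17 and 6.35 in untreated WT and 6.43, 6.43, 9.71 and 8.33 in untreated S534A. After LPS Dbp lay between 7.22 and 9.09 and Arntl between 6.61 and 8.02 in all 8 arrays. With that spread, the LPS change of Dbp was −1.58 ± 0.92 in WT (limma adjusted p = 0.186). It was −3.32 (2.03e-05) without the 3 arrays picked for shifted clock genes, and −1.53 (3.22e-05) with the clock score, which contains Dbp, as covariate. The hour of collection is not given in the sources used here.

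Other splits of the same arrays into 4 and 4 were tested in limma. For LPS, 1 of 35 splits, the real one, gave as many genes in WT (7139, highest other 31), and 1 of 35 in S534A (7225, highest other 0). The real splits thus stood far from all others, though 1 in 35 is the smallest share that such splits can give. Chance cannot be excluded between untreated genotypes, where 5 of 35 splits gave at least the 2 genes found (highest other 1044). After LPS (highest other 1) and in the interaction (highest other 2169) 0 genes were found, so 35 of 35 and 100 of 100 drawn splits gave as many by construction. Nothing follows about chance from these counts. Outside the test set beforehand, the genes at an unadjusted limma p under 0.05 were counted as well. After LPS the real split gave 477, within the 212 to 1838 of the other splits. In the interaction it gave 766, within 177 to 5649, so neither real split stood out. The untreated split with 1044 genes put WT arrays 1 and 3 with S534A arrays 3 and 4, the arrays with the highest Arntl, which points to a structure of the samples other than genotype. Which arrays lay on each side of the drawn split with 2169 was not examined.

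Igfbp1 was higher in untreated S534A than WT livers by 2.00 ± 0.26. A trend with gene length is argued against as the whole cause, since the call stayed with that trend removed (limma adjusted p = 0.00917). The call also stayed with the clock score as covariate (2.01 ± 0.26, limma adjusted p = 0.0139). Untreated clock scores overlapped between genotypes (−1.77 to 3.47 in WT, −2.55 to 3.41 in S534A). The covariate could therefore hardly move the difference, and its test does not decide on collection time. Without the 3 arrays picked for shifted clock genes the Igfbp1 difference was 1.77 ± 0.35 and the call ended (limma adjusted p = 0.383). That left 5 untreated arrays and a larger error, so collection time stays open. Less food before collection, which raises Igfbp1, cannot be told apart from genotype: the lipogenesis list mean differed by 0.042, and its 95% interval of −0.18 to 0.27 allows either sign. The gluconeogenesis list, not part of that test, had a mean of 12.91 in untreated S534A and 12.80 in untreated WT arrays. Its two-sided exact permutation p was 0.0286 (adjusted over the lists 0.4), so less food stays open. An effect of the substitution may remain as a hypothesis, and over all alternatives the adjusted p ran from 4.76e-05 to 0.383.

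In both genotype comparisons 46 genes had an unadjusted p under 0.05 with the same sign, against 21.2 by chance. Of 100 drawn splits 9 gave as many, the real one included (highest other 184), so chance agreement could account for them. DNA from the embryonic stem cells carried along near Rela would place them on its chromosome, where 3 of 46 (6.52%) lay against 553 of 15898 tested genes (3.48%). The odds ratio of 1.94 (95% interval 0.38 to 6.09, Fisher's exact p = 0.215) leaves this open, as 46 genes are too few.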
